A study of Danio rerio with 6 samples.

How the data were processed

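Single cells were sorted from larval zebrafish carrying Tg(mpeg1:mCherry), a transgene in which regulatory sequence of the macrophage gene mpeg1 drives a red fluorescent protein. Per the labels' protocols, larvae of the TL strain were kept in 1-phenyl-2-thiourea, which blocks pigment formation, and the dorsal trunk muscle was punctured with a needle at 4 days post fertilisation. Injured samples came from the dissected injury region at 1, 2 or 3 days post injury (dpi), when the larvae were 5, 6 and 7 days old. The uninjured sample came from whole larvae at 4 days. Live mCherry-positive cells were sorted into 384-well plates and sequenced by SORT-seq, a plate version of CEL-Seq2 that tags each transcript with a molecular identifier and reads its 3' end. The series held 6 libraries, each 1 plate: 1 uninjured, 2 at 1 dpi, 1 at 2 dpi and 2 at 3 dpi. The labels do not say that replicates came from separate groups of animals, so p-values measure the spread between these samples, which may be technical.

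The deposited values are expected counts: the authors' transcript number per gene and well after a correction for identifier collisions, whole at low values and fractional at higher ones. Of the values between 14 and 200, 91.4% equalled a whole number passed through such a correction within 0.011, while 4 values in all lay above the highest that this correction can give. BWA and the Zv9 genome build are named per the submitters' processing notes. The counter, the annotation version and the identifier filter are not given in the sources used here. No other normalization between wells was found in the values. No Zv9 annotation was used here, so no coordinates are given. Gene names came from a table of Ensembl identifiers and symbols, which matched 19001 of 25130 gene identifiers (75.6%, holding 79.2% of the transcripts). Many symbols in it are those of the human counterpart. The symbols il1b, csf1ra and mpx were not in it, whether these genes stand in the files under another symbol was not settled, and under those names they are not analysed here. Its NAMPT (ENSDARG00000030598) and nampt2 (ENSDARG00000027183) are used for the nampt genes. Where several identifiers carry 1 symbol, the identifier is given. Counts of close paralogs, such as the myosin heavy chain genes, are uncertain to the extent that reads could fall on either copy.

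Wells with at least 500 transcripts were kept as cells, 1820 of 2304. Spike-in transcripts, 1.19% to 16.1% of each library, were left out. Kept cells held 1363711 to 8346182 transcripts per library, with median totals per cell of 3018 to 10907. In the uninjured library 18 wells over 50000 transcripts held 70.1% of all transcripts. No doublet caller was run: each well received a sorted event, and such wells were left out as an alternative instead. Counts were rounded to whole numbers and summed per library over all cells, because cells are not replicates. The 2 libraries of 1 dpi differed beyond sampling noise (chi-square per degree of freedom 11.7), as did those of 3 dpi (19.1), so no library was a copy of another.

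Gene-level differences were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by group, robust quasi-likelihood fits and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. The 6 libraries entered 1 fit with a mean per group. The contrasts were 3 dpi minus 1 dpi and the mean of the 3 injured groups minus uninjured. That fit had 2 residual degrees of freedom, a biological coefficient of variation of 45.4% and 13901 tested genes. The lone uninjured and 2 dpi libraries were assumed to vary like the replicated groups. Cells with and without an mmp13a transcript were summed separately in each library after each cell with at least 1000 transcripts was thinned to 1000. Cells were assigned by their counts before thinning. Median totals of positive cells were 10111 against 5863 in the uninjured library and 5336 against 2790 in replicate 1 of 1 dpi. In replicate 2 of 1 dpi and of 3 dpi they were lower (6213 against 8563 and 3628 against 4206). The 2 sums of a library were compared with the library as a block, without mmp13a itself (1673 genes, 5 residual degrees of freedom, coefficient of variation 14%). Gene lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. An estimated correlation was the alternative. Log2 fold changes are given with their standard error (SE).

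The 36 gene lists cover pathways of macrophages and marker genes of macrophages and of other cell types that the sort or tissue could hold. They, the groups, the tests and the rule for named genes were fixed before the data were examined. The rule takes, per comparison and direction, up to 12 called genes with the largest fold change at an average log2 CPM (a gene's counts scaled to the library total) of at least 5. Libraries of the groups must lie apart (for the mmp13a split, every library must show the direction). It adds MPEG1, marco, mmp13a, MMP9, the nampt genes, tnfa and ARG2 in every comparison, and for each list described up to 4 members with the smallest p. A few genes that the rule takes are not reported here. A fold against a group at 0 is computed against a floor of 3 counts over the group and given as a lower bound. With 1 to 3 counts the ratio is given with its 95% counting interval.

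Cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, seed 0), giving 14 clusters. Clusters with a mean macrophage marker level of at least 0.6, a threshold set after seeing the clusters, were named macrophage-like, or microglia-like with at least 3 microglia markers, and more than macrophage markers, among their 50 leading genes. Those with more markers of another cell type than of macrophages or microglia among their 10 leading genes (clusters 1 and 3, 181 and 196 cells) stayed unnamed instead. Clusters below it took the name of another cell type with at least 3 markers among those 50 genes and the most among the 10 leading ones. A cluster that met no condition (cluster 13) stayed unnamed too. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. For a share of 0 the limit given is 3 counts over the cells instead, and for a gene it limits cells with a transcript, not cells that express the gene. With 2 libraries against 2, the smallest p of a two-sided exact permutation test is 0.333, so shares cannot pass a threshold of 0.05.

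Steps were tested on simulated counts drawn from the real means and library sizes. For 3 dpi against 1 dpi (12890 genes) the test recovered 0 of 61 genes changed by log2 1, 17.7% at log2 2 and 50% at log2 3. For injured against uninjured (13025 genes) it recovered 0 of 62, 17.5% and 54.5%. For the mmp13a split (1565 genes) it recovered 78.3%, 100% and 100%. Unchanged genes called numbered 1, 2 and 5. Each gene was drawn at the dispersion trend of the fit and no plate effect was simulated, so false calls in the real data may be more. Alternatives were DESeq2 1.42.0, other scalings and filters, other minimum totals per cell, thinning, leaving out clusters or mitochondrial genes, a replicate block, and leaving out each library. Other cluster settings were tried for shares. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.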

Results

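The series followed macrophages through the repair of a needle injury in the trunk muscle of zebrafish larvae. It asked which macrophage subsets respond to skeletal muscle injury. Transcripts were counted in single mCherry-positive cells from uninjured larvae (1 library, 341 cells) and from injured muscle. The latter gave 299 and 209 cells at 1 dpi, 364 cells at 2 dpi and 276 and 331 cells at 3 dpi. Kept cells of the uninjured library held 8346182 transcripts, those of 1 dpi 1363711 and 1729037, those of 2 dpi 4470936 and those of 3 dpi 1416143 and 1458954. Transcripts of the sorting marker mCherry were found in 15.8% of uninjured cells, 24.1% and 37.3% at 1 dpi, 31.6% at 2 dpi, and 9.06% and 12.4% at 3 dpi.

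Between 1 and 3 dpi transcripts of the cytokine gene tnfa and of the protease gene CTSK fell in the sorted cells of injured muscle, and those of collagen genes rose. The transcript of tnfa (ENSDARG00000009511), a central inflammatory cytokine, fell by 3.18 on the log2 scale (SE 0.69, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.00521, 2 libraries against 2). Its level was 113 and 72.1 CPM (counts scaled to the library total) at 1 dpi, 19.5 and 1.73 CPM at 3 dpi and 5.55 CPM in the uninjured library. CTSK (ENSDARG00000040251), encoding the collagen-degrading lysosomal protease cathepsin K, fell by 3.69 (SE 0.61, edgeR adjusted p = 3.7e-05), from 1037 and 1776 CPM to 145 and 73.8 CPM, against 81.7 CPM in the uninjured library. A gene of collagen matrix moved the other way: COL1A2 (ENSDARG00000020007), a chain of type I collagen, rose by 5.16 (SE 0.72), from 6.26 and 1.14 CPM to 198 and 53.1 CPM. The uninjured library held it at 918 CPM. At 3 dpi, transcripts of fibroblast and connective tissue genes, COL1A2 among them, had a median of 48.1 per well in 13 keratinocyte-like wells of replicate 1 and of 2 and 3 per well in cluster 13 of the 2 replicates. In the other clusters of at least 10 wells the median was 0 or 1.

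Further genes that rose between 1 and 3 dpi were SPARC, a collagen-binding matrix glycoprotein (log2 change 5.05, SE 0.79), COL11A1, a fibrillar collagen chain (4.68, SE 1.00), and si:ch211-105c13.3 (4.68, SE 0.75). Several others were nearly undetected at 1 dpi. COL12A1 (ENSDARG00000019601), a collagen found with type I fibrils, was 84.2-fold higher (95% counting interval 14.7 to 3364). CEBPD, a transcription factor of the C/EBP family, was 45.2-fold higher (12.1 to 379). The keratin krt15 was 38-fold higher (6.4 to 1540) and the basement membrane collagen col4a5 23.6-fold (6.2 to 201). A gene without a symbol, ENSDARG00000061219, was 161-fold higher (28.5 to 6404). Counts of 0 at 1 dpi gave lower bounds for SERPINH1 (ENSDARG00000019949), a collagen chaperone (at least 6.2-fold), atp2a1l, a calcium pump (at least 3.1-fold), and igfn1.1 (at least 2.1-fold). These bounds rest on 18, 9 and 6 counts at 3 dpi. Levels there were 5.70 and 6.34 CPM, 6.51 and 0.58 CPM, and 3.26 and 1.15 CPM. Their average over the 6 libraries met the rule through the uninjured library, at 578, 727 and 206.5 CPM.

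Other genes that fell were dicp2.1, encoding an immunoglobulin-domain receptor (-4.27, SE 0.68), LRPAP1, a chaperone of lipoprotein receptors (-3.68, SE 0.65), PDIA4, a disulfide isomerase of the endoplasmic reticulum (-3.45, SE 0.57), and the transporter gene ABCB4 (-3.07, SE 0.59). CD276, of the B7 family of immune regulators (-3.01), the galectin gene lgals9l1 (-2.97), FN1 (ENSDARG00000019815), encoding fibronectin (-2.89), si:dkey-6n3.3 (-3.43) and si:busm1-57f23.1 (-3.31) fell as well. The macrophage gene MPEG1 had a log2 difference of -1.09 at ENSDARG00000055290 (edgeR adjusted p = 0.156) and fell by 3.1 at its lower-count copy ENSDARG00000043093 (edgeR adjusted p = 0.019). Values for the scavenger receptor marco (-0.37, adjusted p = 0.656) and the collagenase mmp13a (0.74, 0.401) did not pass the edgeR test. Nor did those for the gelatinase MMP9 (1.09, 0.212), the arginase ARG2 (1.13, 0.133), NAMPT (0.12, 0.901), encoding the enzyme that starts NAD salvage, or nampt2 (-0.48, 0.747). Without clusters of other cell types marco was at 0.12 and NAMPT at -0.19, and without replicate 2 of 1 dpi nampt2 was at 0.55.

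Of 36 gene lists, 9 passed the camera test between 1 and 3 dpi. None did with an estimated correlation between genes, where the smallest adjusted p was 0.852. Among 70 measured genes of oxidative phosphorylation, the mitochondrial respiratory chain, 32 fell, 0 rose and 38 did not pass, with 54 called when adjusted over the list alone. Their median log2 change was -1.53 (camera adjusted p = 1.86e-21; adjusted p = 0.898 with an estimated correlation). Examples were cox6b1 (-2.95), atp5mc1 (-2.79), SDHD (-2.45) and atp5mf (-2.13), subunits of respiratory complexes and ATP synthase. Of 38 cell cycle genes 16 fell and 0 rose (26 adjusted over the list alone, median -2.20, camera adjusted p = 1.77e-14; adjusted p = 0.852 with an estimated correlation). The mitotic kinase genes CDK1 (-3.53) and plk1 (36-fold lower, 95% counting interval 9.6 to 303), the histone gene h2ax (-3.46) and the chromatin gene hmgb2b (-2.23) were among them. Of 40 lysosome genes 11 fell, 0 rose and 29 did not pass (17 adjusted over the list alone, median -1.18, camera adjusted p = 5.25e-10; adjusted p = 0.898 with an estimated correlation). They included CTSK and proton pump subunits: ATP6V1A at its 2 identifiers (-2.04 and -1.94) and atp6v1e1b (-2.03). The direction of the oxidative phosphorylation, cell cycle and lysosome medians was the same under each scaling tried, but the counts were not. With RLE 15, 12 and 8 genes of the 3 lists were lower, with library size alone 3, 2 and 4, and with DESeq2 26, 9 and 17. Each of these lists was called with any 1 of the 6 libraries left out.

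**Figure D1:**
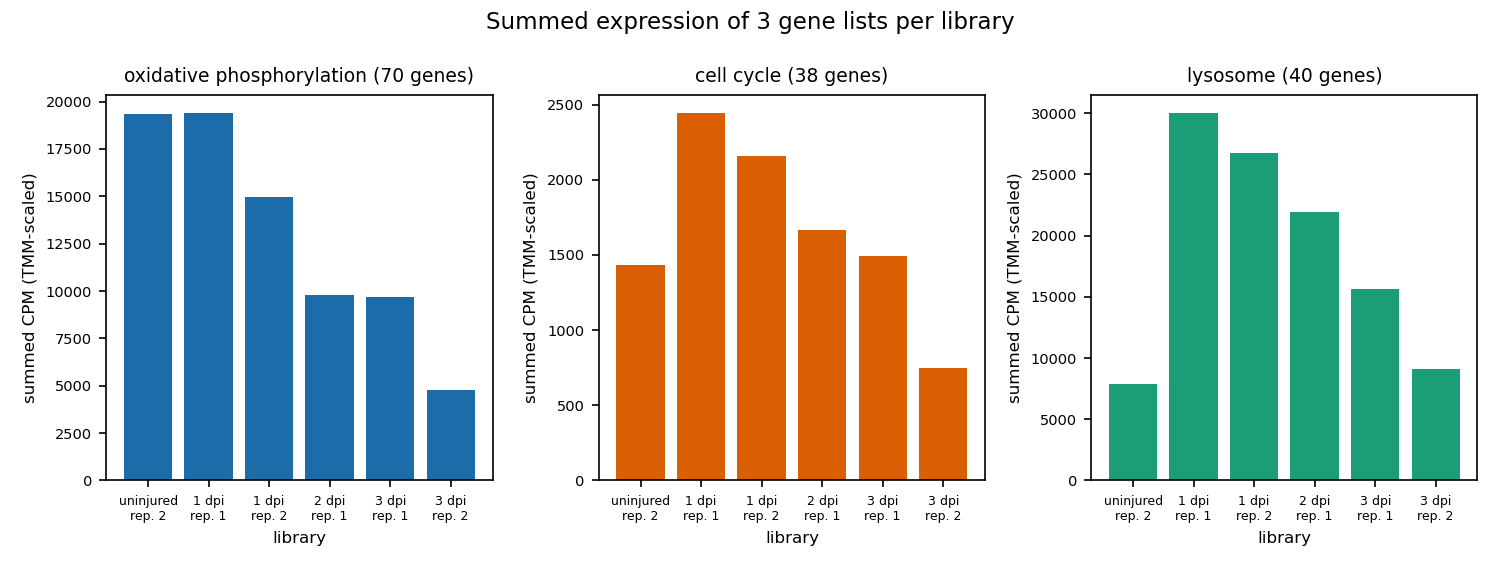
Summed expression in TMM-scaled CPM of the measured genes of 3 lists, 1 bar per library, on axes that start at 0. The 3 dpi libraries lie below both 1 dpi libraries in each list, with oxidative phosphorylation at 9700 and 4783 CPM against 19377 and 14972 CPM.

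Marker genes of other tissues also moved between 1 and 3 dpi. Of 24 fibroblast and connective tissue genes 8 rose and 16 did not pass (14 adjusted over the list alone, median 3.01, or 2.51 with genes at 0 set to their bounds). The camera adjusted p was 3.92e-06 (adjusted p = 0.852 with an estimated correlation), and the small matrix proteoglycan gene FMOD (ENSDARG00000010294, 3.73) rose beside the collagens. Of 22 keratinocyte genes 5 rose (7 adjusted over the list alone, median 3.40, with bounds 3.68, camera adjusted p = 0.00201; adjusted p = 0.898 with an estimated correlation). The adhesion gene epcam (3.93) and the desmosome genes evpla (3.54) and DSP (2.80) were among them. Of 36 skeletal muscle genes 8 rose (11 adjusted over the list alone, median 1.9, with bounds 1.64, camera adjusted p = 0.0192; adjusted p = 0.898 with an estimated correlation), such as AK1, an adenylate kinase (2.84), and the giant sarcomere gene TTN (3.59 and 2.71 at its 2 identifiers). Metaphocytes are skin-resident cells that resemble macrophages: 4 of their 7 markers rose (4 adjusted over the list alone, median 1.78, camera adjusted p = 0.0399; adjusted p = 0.898 with an estimated correlation), among them the junction genes cldn7b (3.74) and f11r.1 (1.78) and the protease inhibitor gene spint2 (4.19). The macrophage list had 3 genes that rose, 3 that fell and 20 that did not pass (7 adjusted over the list alone, median -0.42, camera adjusted p = 0.0495; adjusted p = 0.898 with an estimated correlation). The invariant chain genes cd74a (3.13) and cd74b (2.64), which serve antigen presentation, and ms4a17a.11 (2.29) rose while lgals9l1 fell. Of 10 endothelial genes 0 passed, with 0 adjusted over the list alone (median 1.80, with bounds 1.39, camera adjusted p = 0.0315; adjusted p = 0.898 with an estimated correlation). That list was called in 0 of 6 fits that each left out 1 library (adjusted p up to 0.197, without the uninjured library). Without replicate 1 of 3 dpi the keratinocyte (median 0.83, adjusted p = 0.507), skeletal muscle (0.61, 0.287) and metaphocyte (1.54, 0.694) lists lost their call. Left-out libraries moved these medians between 0.83 and 5.21, 0.42 and 2.26, and 1.54 and 5.34, that of the endothelial list between 1.00 and 2.07 and that of the macrophage list between -0.78 and -0.16. With library size alone 3 fibroblast, 2 keratinocyte, 3 skeletal muscle, 1 metaphocyte and 1 macrophage genes were higher, and with RLE 5 skeletal muscle genes. Summed levels lay apart for fibroblast genes (89.1 and 63 CPM at 1 dpi, 1363 and 489 CPM at 3 dpi). Those of endothelial genes did too (69.6 and 71.5, then 152 and 175 CPM). Sums overlapped for skeletal muscle (979 and 813, then 1246 and 762 CPM). So did those for keratinocyte (7073 and 3882, then 20849 and 4197 CPM) and metaphocyte genes (1219 and 913, then 2095 and 1005 CPM). Of the 36 skeletal muscle genes 11 had too few counts for a fold. The macrophage list lost its call without replicate 1 of 1 dpi (0.124), 2 dpi (0.0515), replicate 2 of 3 dpi (0.453) or the uninjured library (0.141). The 27 other lists had camera adjusted p-values of 0.0577 to 0.992. Among them, inflammatory mediators had a median of -0.31 and a mean of 0.02, matrix proteases a median of 0.35, and alternative activation genes a median of 0.02.

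In all, 1254 of 13901 genes were called between 1 and 3 dpi by edgeR, 771 higher and 483 lower (61.5% higher). DESeq2 called 615 (50.7% higher), edgeR with RLE factors 664, with library size alone 70 (32.9% higher) and with cells thinned to 1000 transcripts 643. The fit of only the 4 libraries of 1 and 3 dpi called 0, with 2555 genes at an unadjusted p under 0.05. The count also rested on single libraries: it was 108 without replicate 1 of 1 dpi, 14 without replicate 2 of 1 dpi, 793 without 2 dpi, 3852 and 735 without replicate 1 or 2 of 3 dpi, and 559 without the uninjured library. Without replicate 2 of 1 dpi, 3 of the 12 rising and 5 of the 12 falling genes named by size were still called. Cells moved with the times as well. Without the neutrophil-like cluster 787 genes were called, and without an unnamed cluster (cluster 13) that held 50 of 331 cells in replicate 2 of 3 dpi and 11, 6, 2, 1 and 0 cells elsewhere, 528 (36.4% higher). With thinned cells and without clusters of other cell types 524 were called: all 12 falling genes named by size, tnfa and CTSK included, were still called and 0 of the 9 rising ones that could be tested.

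Shares of several cell classes were measured at each time. Neutrophil-like cells, defined by npsn, EPX, MMP9 and mmp13a among other genes, made up 1.47% of uninjured cells (5 of 341), 10.4% and 10.05% at 1 dpi, 17.3% at 2 dpi, and 21.4% and 24.2% at 3 dpi. The means were 10.2% ± 0.23 (SD, n = 2) and 22.8% ± 1.97 (SD, n = 2), a difference of 12.6 points (two-sided exact permutation p = 0.333, the smallest this design allows). Clustering without the genes changed between the times gave 12.4 points. Metaphocyte-like cells, led by grna.2, cldn3c and spint2, made up 3.52% of uninjured cells. They formed 1.67% (5 of 299) and 0% (0 of 209, which allows a share of up to 1.44%) at 1 dpi, 0.55% at 2 dpi, and 5.80% and 6.65% at 3 dpi (difference 5.39 points, pooled SD 0.94, exact permutation p = 0.333). Keratinocyte-like shares of the 2 times overlapped, with 2.01% and 0% at 1 dpi (up to 1.44%) and 4.71% and 1.21% at 3 dpi. Macrophage-like cells, clustered without the genes changed between the times, made up 71.8% at 1 dpi and 49.7% at 3 dpi on average (difference -22.05 points, pooled SD 5.66, exact permutation p = 0.333). Over all 6 cluster settings that difference lay between -4.61 and -36.66 points. Cells of unnamed clusters, with the settings used elsewhere, made up 54.3% of the uninjured library, 22.7% and 5.26% at 1 dpi, 3.85% at 2 dpi, and 36.6% and 20.5% at 3 dpi. Unnamed does not mean other than macrophages. Cluster 1, with 181 uninjured cells, had a mean macrophage marker level of 1.01, above the threshold of 0.6. Cluster 3 stood at 0.74 and held 66 and 10 cells at 1 dpi and 90 and 18 at 3 dpi (replicates 1 and 2). The sort was on mpeg1:mCherry, so these shares are of sorted cells, not of the tissue.

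**Figure D2:**
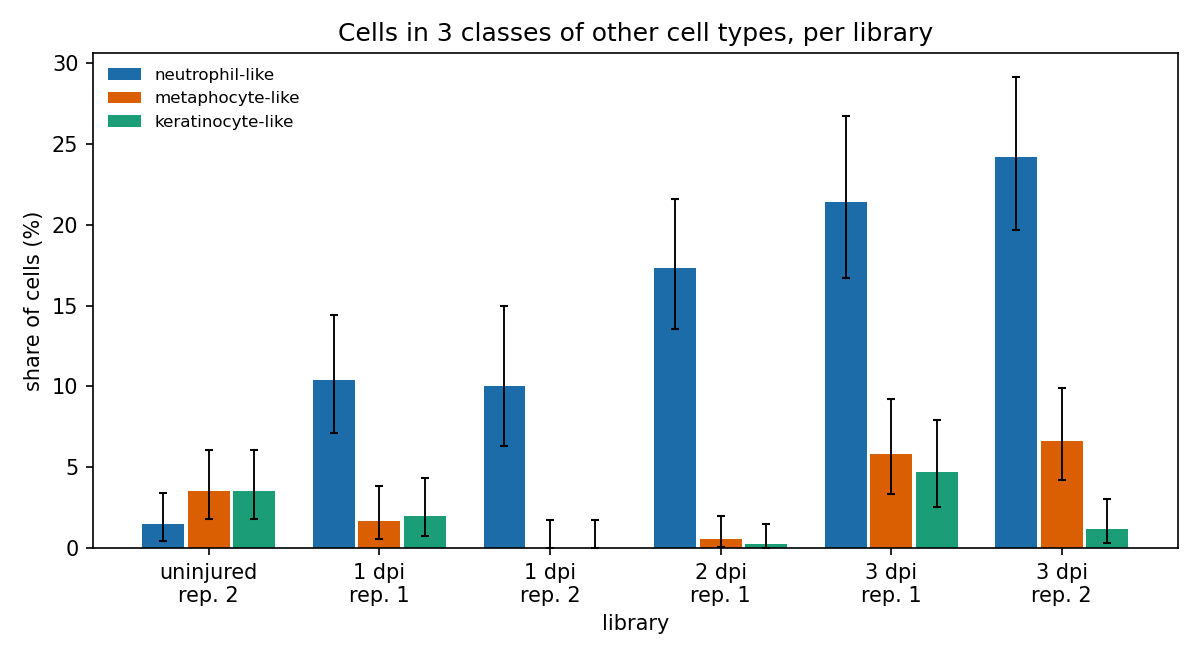
Share of cells (%) in 3 classes of other cell types per library; bars are shares of cells with at least 500 transcripts and error bars exact 95% intervals (counting error only). Neutrophil-like cells stand at 10.4% and 10.05% in the 1 dpi libraries and at 21.4% and 24.2% in the 3 dpi libraries.

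Genes used as markers of macrophage states were counted per cell after thinning to 1000 transcripts. A transcript of mmp13a was seen in 7.82% of 294 uninjured cells, 22.2% and 13.8% at 1 dpi, 26.1% at 2 dpi, and 29.1% and 34% at 3 dpi. Over thinned cells of every class, the 3 dpi mean was 13.6 points above that of 1 dpi (pooled SD 4.87, exact permutation p = 0.333). For tnfa the shares were 0.68% uninjured, 4.89% and 8.16% at 1 dpi, 2.56% at 2 dpi, 0.40% in replicate 1 of 3 dpi and 0 of 300 cells in replicate 2, which allows up to 1.00% (difference -6.32 points, pooled SD 1.65, exact permutation p = 0.333). ARG2 was found in 2.38% of uninjured cells, 6.02% and 4.08% at 1 dpi, 6.25% at 2 dpi, and 6.77% and 14% at 3 dpi. NAMPT lay between 11.65% and 14.7% in all 6 libraries. Thinning kept 294 cells of the uninjured library and 266, 196, 352, 251 and 300 of the injured ones. Without thinning all cells counted, and the shares were 21.99%, 41.8%, 26.3%, 51.1%, 41.3% and 47.4% for mmp13a and 3.81%, 13.7%, 16.7%, 16.2%, 3.26% and 0.60% for tnfa, in the same order. They were 12.6%, 13.7%, 12.9%, 18.96%, 16.7% and 25.98% for ARG2 and 41.9%, 28.1%, 44.98%, 58.2%, 33.7% and 34.1% for NAMPT.

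In each of the 5 injured libraries mmp13a, ARG2 and NAMPT were found in the largest share of neutrophil-like cells, among classes of at least 10 cells there. For mmp13a this was in part built in, since it is among the leading genes of that cluster. After thinning, over the injured libraries together, mmp13a was found in 224 of 235 neutrophil-like cells (95.3%), 90 of 773 macrophage-like cells (11.64%) and 0 of 43 metaphocyte-like cells (which allows up to 6.98%), with median totals of 4022, 7615 and 3834 transcripts before thinning. ARG2 was found in 31.1% of neutrophil-like and 2.85% of macrophage-like cells, and NAMPT in 30.6% and 9.70%. By library, mmp13a was seen in 15.29% and 6.21% of macrophage-like cells at 1 dpi and in 11.48% and 14.52% at 3 dpi. These values of the times overlapped, so no rise within macrophage-like cells was seen. In neutrophil-like cells the values were 95.83% and 100% at 1 dpi and 92.73% and 94.74% at 3 dpi. A tnfa transcript was seen in 32 of 773 macrophage-like cells (4.14%) and in 0 of 235 neutrophil-like cells (up to 1.28%), counts that mix times with different tnfa levels and class shares. Within libraries it was seen in 5.29% and 9.32% of macrophage-like cells at 1 dpi, 3.11% at 2 dpi and 0 of 61 and 124 at 3 dpi. Macrophage-like cells had the largest share in 0 of 5 libraries, but the leading classes rested on few cells. These were 4 of 54 and 1 of 10 cells at 1 dpi, 1 of 13 at 2 dpi and 1 of 89 in replicate 1 of 3 dpi. In replicate 2 of 3 dpi no class held a tnfa transcript. Different clusters held most macrophage-like cells at each time: clusters 4 and 10 at 1 dpi, cluster 8 at 2 dpi and clusters 5 and 11 at 3 dpi. Leading genes of some of these clusters are genes called between 1 and 3 dpi: si:dkey-6n3.3 in clusters 4 and 10, CTSK in cluster 10 and cd74a in cluster 5. The clusters thus partly restate the differences between libraries and are no separate evidence of a change. In the uninjured library mmp13a was found in 2 of 57 skeletal muscle-like cells (3.51%, median total 2175).

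**Figure D3:**
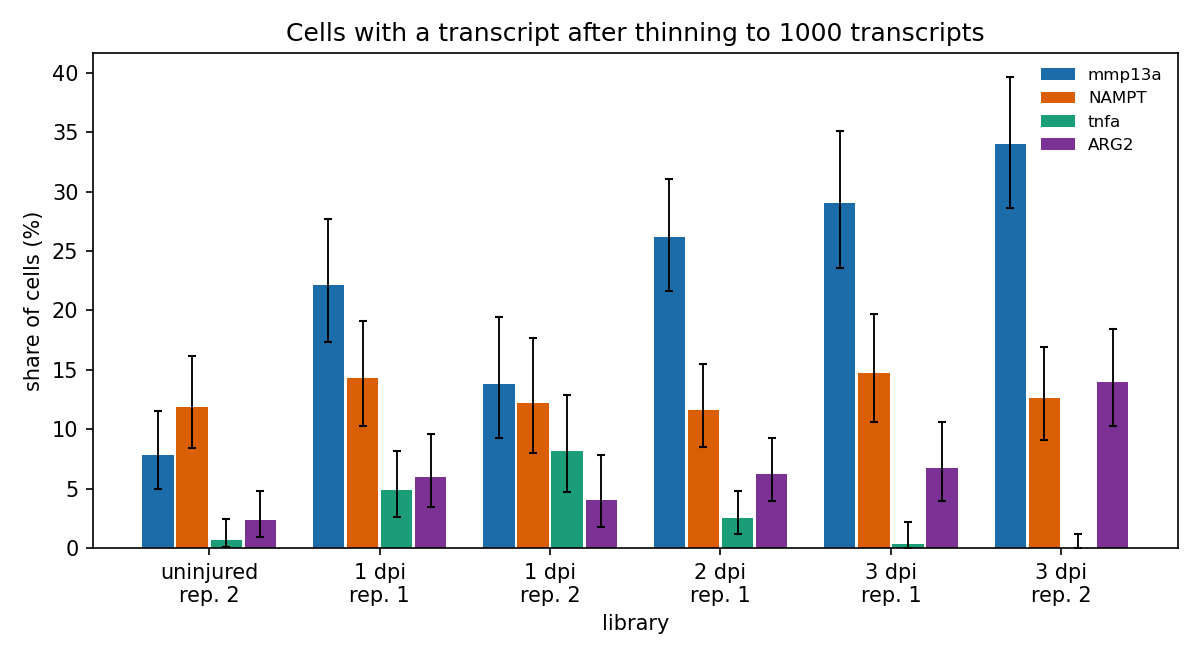
Share of cells (%) with at least 1 transcript of mmp13a, NAMPT, tnfa or ARG2 per library after thinning each cell to 1000 transcripts; error bars are exact 95% intervals (counting error only). The tnfa bars are 4.89% and 8.16% at 1 dpi and 0.40% and 0% at 3 dpi, while NAMPT stays between 11.65% and 14.7%.

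Injured muscle was compared with uninjured larvae as the control of the design. EPX, npsn, MMP9 and the cytokine gene tnfb were higher in each injured library. EPX (ENSDARG00000019521), a granulocyte peroxidase gene, was 5.44 higher on the log2 scale (SE 0.86, edgeR adjusted p = 1.93e-07, 5 injured libraries against 1), at 443 to 1070 CPM against 15.6 CPM. The neutrophil protease gene npsn was 3.90 higher (SE 0.78) and MMP9 3.73 higher (SE 0.83). The value was 3.71 for tnfb (SE 0.81). Also called were tnfa (2.57, SE 0.81), which at 1.73 CPM in replicate 2 of 3 dpi lay below the 5.55 CPM of the uninjured library, and mmp13a (3.01, SE 0.77), whose value was -0.0083 in thinned cells without clusters of other cell types. Muscle genes were far lower: the fast myosin gene myhz1.1 (ENSDARG00000067990) was 13446-fold lower (95% counting interval 3722 to 111032).

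Other genes higher in injured muscle were ppp1r3c2b, a regulator of glycogen synthesis (4.33), scpp8 (3.98), the immune receptor genes dicp2.1 (3.86) and dicp1.1 (3.81), the aminopeptidase gene anpepla (3.85) and NOCT (ENSDARG00000078525), encoding nocturnin (3.77). The 4 others named by size carry no symbol: ENSDARG00000089319 (5.64), ENSDARG00000041524 (4.22), ENSDARG00000075335 (4.03) and ENSDARG00000070398 (3.90). Among the lower genes were the myosins myhz2 (at least 2674-fold) and myhz1.2 (10604-fold, 2935 to 87565), the calcium buffer gene pvalb4 (4737-fold, 1311 to 39119) and the myosin light chain gene MYL11 at ENSDARG00000002589 (-12.50). So were the mitochondrial carrier gene SLC25A4 (at least 1490-fold), the cone opsin genes opn1lw2 (at least 1112-fold) and OPN1SW (-12.47), zgc:153968 (at least 1287-fold), the fatty acid carrier gene FABP1 (at least 865-fold) and afp4 (at least 837-fold). Values for MPEG1 (1.31 at ENSDARG00000055290, edgeR adjusted p = 0.149; 0.53 at ENSDARG00000043093, 0.809), marco (1.22, 0.178), NAMPT (0.95, 0.317), nampt2 (-0.31, 0.901) and ARG2 (1.11, 0.221) did not pass. Without clusters of other cell types MPEG1 was at -0.095 and -0.58, marco at -0.18 and NAMPT at -0.20, and with the replicate block nampt2 was at 0.033.

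Markers of other tissues formed the lower lists, and the uninjured library came from whole larvae. Of 36 skeletal muscle genes 34 fell and 0 rose (34 adjusted over the list alone, median -10.25, camera adjusted p = 1.52e-47; adjusted p = 0.174 with an estimated correlation). Summed, they took 81345 CPM in the uninjured library against 762 to 1246 CPM in injured ones. Of 28 neuron and glia genes 26 fell (27 adjusted over the list alone, median -5.78, with bounds -5.44, camera adjusted p = 2.84e-18; adjusted p = 0.193 with an estimated correlation), such as FABP7 (ENSDARG00000007697, -6.90) and GPM6A (ENSDARG00000055455, -8.00). Of 14 pancreas and gut genes 13 fell (14 adjusted over the list alone, median -7.76, 9.11e-17; adjusted p = 0.174 with an estimated correlation), such as FABP2 (-9.11) and the elastase gene CELA1 (-7.56). Of 24 fibroblast genes 18 fell (20 adjusted over the list alone, median -4.47, 8.98e-15; adjusted p = 0.174 with an estimated correlation), such as DCN, encoding decorin (-5.13), and COL6A2 (-4.41). Of 16 hepatocyte and yolk genes 13 fell (15 adjusted over the list alone, median -7.11, with bounds -6.25, 2.63e-13; adjusted p = 0.193 with an estimated correlation), such as RBP2 (ENSDARG00000070038, -8.40) and apoa2 (1388-fold, 475 to 6735). Of 22 keratinocyte genes 11 fell (11 adjusted over the list alone, median -3.95, 1.46e-06; adjusted p = 0.353 with an estimated correlation), such as krt15 (-5.87) and agr1 (-7.03). Of 13 pigment cell genes 9 fell (10 adjusted over the list alone, median -7.16, with bounds -5.45, 2.84e-06; adjusted p = 0.353 with an estimated correlation), such as the melanosome gene pmela (-8.03) and TYRP1 (ENSDARG00000056151, 1064-fold, 294 to 8794). Of 7 metaphocyte genes 4 fell (5 adjusted over the list alone, median -3.07, 0.00613; adjusted p = 0.385 with an estimated correlation), with epcam (-3.14) and krt18a.1 (-3.60). Of 12 erythroid genes 5 fell (5 adjusted over the list alone, median -1.87, 0.00613; adjusted p = 0.353 with an estimated correlation), with the globin gene hbae3 (-8.69) and the heme synthesis gene alas2 (-3.17; 0.39 in thinned cells without other cell types). Of 6 muscle progenitor genes 4 fell (4 adjusted over the list alone, median -2.59, 0.0411; adjusted p = 0.353 with an estimated correlation), with the myogenic factor genes MYOD1 (-2.83; 0.12 without other cell types and wells over 50000 transcripts) and MYOG (-4.37). Left-out libraries moved the erythroid median between -4.30 and -1.56 and the metaphocyte median between -3.79 and -2. The number lower was 8 with library size and 7 with DESeq2 for hepatocyte and yolk genes, 2 with DESeq2 for erythroid genes, and 2 with RLE, 1 with library size and 0 with DESeq2 for muscle progenitor genes. In oxidative phosphorylation 16 of 70 genes fell (19 adjusted over the list alone, median -1.07, 1.43e-05; adjusted p = 0.655 with an estimated correlation), with cox6b1 (-2.87) and the muscle isoform gene cox7a1 (-3.86). DESeq2 called 3 of them lower, and the median turned to 0.054 without clusters of other cell types, 0.010 without wells over 50000 transcripts and 0.080 without both.

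The lists higher in injured muscle were those of several immune cell types and of the lysosome, immune signals, matrix proteases, alternative activation and growth factors. Wells over 50000 transcripts held most transcripts of the uninjured library, and its TMM factor was 0.98. Genes scarce in these wells thus read lower in that library after scaling to its total. This alone would raise such genes together in injured muscle, so injury is not shown as the cause of these rises. Without these wells MPEG1 (ENSDARG00000055290) was at -0.12 and marco at -0.21, while the 12 higher genes named by size were still called. Of 17 neutrophil genes 11 rose and 0 fell (13 adjusted over the list alone, median 2.11, camera adjusted p = 1.37e-08; adjusted p = 0.353 with an estimated correlation). Of 26 macrophage genes 4 rose (13 adjusted over the list alone, median 1.48, 1.25e-08; adjusted p = 0.353 with an estimated correlation): lgals9l1 (2.02), the myeloid transcription factor gene SPI1 (1.89), CORO1A (1.98) and ptprc (1.82). In thinned cells without clusters of other cell types SPI1 was at -0.029, ptprc at -0.11 and the macrophage median at -0.11. Of 40 lysosome genes 2 rose, CTSK (2.82) and TPP1 (1.69), and the proton pump gene ATP6V0C (ENSDARG00000036577) fell (-6.70; 2 adjusted over the list alone, median 1.38, 2.73e-08; adjusted p = 0.353 with an estimated correlation). Of 17 antigen presentation genes 3 rose (4 adjusted over the list alone, median 1.41, 1.43e-05; adjusted p = 0.283 with an estimated correlation): the costimulatory receptor gene cd40 (2.48), b2m (2.51) and CD276 (2.05). Of 19 genes of inflammatory mediators 6 rose and 1 fell (10 adjusted over the list alone, median 1.54, 0.000133; adjusted p = 0.353 with an estimated correlation), with tnfb, il12a (3.65) and nfkbiab (2.30) up and the prostaglandin synthase gene PTGS2 (ENSDARG00000004539, -2.70) down. Of 25 chemokine and receptor genes 7 rose and 4 fell (16 adjusted over the list alone, median 1.88, 0.000202; adjusted p = 0.353 with an estimated correlation), with CCR9 (3.37) and CXCR4 (ENSDARG00000057633, 3.38) up and CXCL12 (-4.12) and ccl25b (-3.51) down. Of 10 microglia genes 1 rose, ENTPD1 (1.71; 4 adjusted over the list alone, median 1.38, 0.000214; adjusted p = 0.353 with an estimated correlation). Of 20 interferon genes 1 rose, IRF7 (2.38; 1 adjusted over the list alone, median 0.93, 0.000894; adjusted p = 0.353 with an estimated correlation). Of 22 matrix protease genes 5 rose and 2 fell (9 adjusted over the list alone, median 0.89, 0.001; adjusted p = 0.347 with an estimated correlation), with TIMP2 (ENSDARG00000061226), a protease inhibitor gene, down (-3.21). Of 33 genes of alternative activation 6 rose and 4 fell (12 adjusted over the list alone, median 0.58, mean -0.00, 0.0245; adjusted p = 0.353 with an estimated correlation), with tgfb1b up (2.2) and MAF (-5.81) and TGFB3 (-4.40) down. Of 11 dendritic genes 0 rose and 1 fell, SPOCK3 (-2.19; 1 adjusted over the list alone, median 0.65, 0.0315; adjusted p = 0.353 with an estimated correlation). Of 14 growth factor genes 2 rose and 1 fell (6 adjusted over the list alone, median 0.78, 0.0491; adjusted p = 0.353 with an estimated correlation), with m17, of the interleukin 6 family, up (2.88) and hbegfa down (-2.49). The growth factor median was -0.26 without other cell types and wells over 50000 transcripts, and the microglia test turned down (median 0.17) in thinned cells without other cell types. Scaling moved several of these counts. Of lysosome genes 6 were higher with RLE, 14 with library size and 15 with DESeq2, and of macrophage genes 12 with library size and 12 with DESeq2. Microglia genes had 2 higher in each of these fits, antigen presentation genes 5 with DESeq2, and dendritic genes 1 higher and 0 lower with library size or DESeq2. The number lower was 2 with library size and 1 with DESeq2 for alternative activation, 2 with DESeq2 for chemokines, and 1 with library size and 0 with DESeq2 for matrix proteases. The 13 other lists had camera adjusted p-values of 0.0552 to 0.989, among them cell cycle genes with a median of -0.31.

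In all 2317 genes were called by edgeR, 321 higher and 1996 lower in injured muscle (13.9% higher), and DESeq2 called 1142 (32.6% higher). Injury, dissection and age changed together in this comparison, and wells named skeletal muscle-like made up 27.9% of the uninjured library and 0 of 299, 209, 364, 276 and 331 cells of the injured ones (up to 1.44%). Of the 95 muscle-like wells, 9 held over 50000 transcripts each and together 92.5% of the muscle transcripts of that library. The 86 others held a median of 56 muscle transcripts among 1085, against 67.55 among 8078 in wells of unnamed cluster 1 up to 50000 transcripts. Without clusters of other cell types 348 genes were called, without wells over 50000 transcripts 484, and with cells thinned to 1000 transcripts 197. Of the 12 higher genes named by size 5 were still called without clusters of other cell types, and 1 of the 9 that could be tested with cells thinned as well. The macrophage (adjusted p = 0.63), lysosome (0.368), inflammatory mediator (0.0711), chemokine (0.678), microglia (0.368), interferon (0.0711), matrix protease (0.704), alternative activation (0.368), dendritic (0.49), growth factor (0.845), muscle progenitor (0.845), pigment cell (0.128) and oxidative phosphorylation (0.271) lists then lost their camera call. The count was 1532 and 1392 without replicate 1 or 2 of 1 dpi, and 4061 and 3922 without replicate 1 or 2 of 3 dpi. Without replicate 1 of 1 dpi the alternative activation (0.0699), dendritic (0.0592) and growth factor (0.0832) lists lost their call, and without replicate 1 of 3 dpi the same lists did (0.0537, 0.0537 and 0.0852). Without 2 dpi the dendritic (0.0548) and metaphocyte (0.0661) lists did, and the muscle progenitor list was called in 1 of 5 such fits (0.0863 without replicate 2 of 1 dpi, 0.102 without 2 dpi, 0.0955 and 0.071 without replicate 1 or 2 of 3 dpi).

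Cells with an mmp13a transcript were compared with those without, within each of the 6 libraries, to describe the cells this marker labels. Higher in mmp13a-positive cells were EPX by 5.22 on the log2 scale (SE 0.21, edgeR adjusted p = 3.95e-20), npsn by 4.95 (SE 0.20) and MMP9 by 4.67 (SE 0.13), each in all 6 libraries. Among the lower genes were the apolipoprotein genes apoc1 (-2.12, SE 0.18) and apoeb (-1.82, SE 0.12), and the protease genes LGMN (-1.14, SE 0.16) and ctsla (-1.12, SE 0.12). ARG2 was 2.82 higher (SE 0.33) and NAMPT 1.09 higher (SE 0.23; -0.13 without the neutrophil-like cluster and -0.019 without all clusters of other cell types), while MPEG1 (ENSDARG00000055290) fell by 0.64 (SE 0.17, edgeR adjusted p = 0.00514). The value for marco, -0.50, did not pass (0.062) and was 0.044 without clusters of other cell types.

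Other genes higher in mmp13a-positive cells were ppdpfa (3.82), the sulfotransferase gene sult5a1 (3.31), cfbl (2.81) and limd2 (2.43). Identifiers without a symbol were ENSDARG00000041524 (4.47), ENSDARG00000070398 (2.75), ENSDARG00000027852 (2.43) and ENSDARG00000057430 (2.39). Lower genes were the solute carriers SLC43A3 (-1.47), SLC43A2 (ENSDARG00000061120, -1.23) and SLC35F6 (-1.11) and the endocytic receptor gene LRP1 (-1.32). The chemokine gene ccl34b.1 (-1.16), paox1 (-1.11) and ENSDARG00000054921 (-1.22) were lower too.

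**Figure D4:**
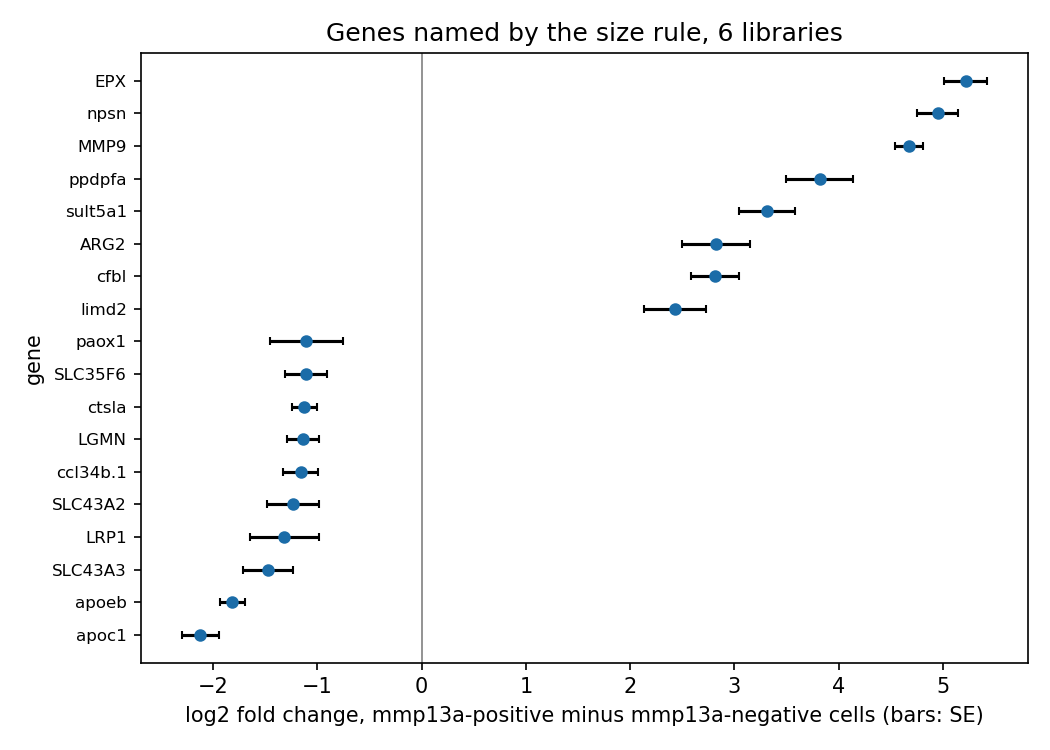
Log2 fold change between mmp13a-positive and mmp13a-negative cells for genes with a symbol that were named by size; points are edgeR estimates over 6 libraries and bars their SE. EPX lies at 5.22 and apoc1 at -2.12.

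Of 21 lists 7 passed in the mmp13a split. Of 9 neutrophil genes 7 rose and 0 fell (7 adjusted over the list alone, median 1.3, camera adjusted p = 6.53e-28; adjusted p = 0.0271 with an estimated correlation), with LECT2 (1.99) and the granule proteoglycan gene srgn (1.3). Of 30 lysosome genes 19 fell and 0 rose (23 adjusted over the list alone, median -0.60, 1.72e-09; adjusted p = 0.0662 with an estimated correlation), with CTSD (-0.82) and PSAP (-0.72). Of 7 microglia genes 5 fell (6 adjusted over the list alone, median -0.90, 5.03e-08; adjusted p = 0.0662 with an estimated correlation), apoc1, apoeb and ccl34b.1 among them. Of 11 lipid handling genes 4 fell and 1 rose (6 adjusted over the list alone, median -0.36, 0.00193; adjusted p = 0.18 with an estimated correlation): the cholesterol transfer gene NPC2 fell (-0.93) and ACSL4 (ENSDARG00000010752), a fatty acid ligase gene, rose (1.26). Left-out libraries moved that median between -0.48 and -0.23. Of 8 matrix protease genes 4 rose and 3 fell (7 adjusted over the list alone, median 0.22, 0.00196; adjusted p = 0.0794 with an estimated correlation), with the other TIMP2 gene (ENSDARG00000075261) up (1.03), though not in the uninjured library (233 against 306 CPM). Leaving out single libraries moved the matrix protease median between -0.24 and 0.42. Of 19 macrophage genes 10 fell and 2 rose (14 adjusted over the list alone, median -0.50, 0.00871; adjusted p = 0.414 with an estimated correlation), with MFAP4 (ENSDARG00000090783, -0.73) and cd74a (-1.17, but 68.1 against 23.9 CPM in replicate 1 of 1 dpi) down and the transcription factor gene CEBPB up (0.40). Of 11 glycolysis genes 3 rose (5 adjusted over the list alone, median 0.44, 0.0104; adjusted p = 0.267 with an estimated correlation), ALDOC (1.15), GAPDHS (0.53) and GPI (0.90). GPI was not higher in the uninjured library (233 against 259 CPM) and was at -0.25 without the neutrophil-like cluster and -0.14 without clusters of other cell types. The 14 other lists had camera adjusted p-values of 0.0718 to 0.956.

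In all 271 of 1673 genes differed, 135 higher and 136 lower, and DESeq2 called 155 (57.4% higher). Neutrophil-like cells stood within this split: 254 of 259 of them carried mmp13a, against 458 of 1561 other cells. Part of that overlap was built in, since mmp13a is among the leading genes of their cluster. Without that cluster 12 genes were called, 1 of the 12 higher genes named by size could still be tested, and of the 7 lists the macrophage (adjusted p = 0.0943) and matrix protease (0.819) lists lost their call. The count was 83 without thinning, 41 without the library block, 11 without clusters of other cell types, and 180 and 178 without replicate 1 or 2 of 3 dpi. Detection of 1 transcript is a range, not a type: 17 to 60 of the positive cells per library held exactly 1.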

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

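All tests weighed in this part and the test of how the mmp13a difference changes with time were chosen after the results were seen; only the rule for a library far from the others was set earlier.

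Of 33 values tested in the 5 injured libraries, 3 had a library far from the others, where chance puts about 1 in 20. The immune receptor gene dicp1.1 stood at 313 CPM in the 2 dpi library, against 32.9 CPM in the next. The muscle gene pvalb4 was at 0.45 CPM in the 2 dpi library and at 0 in the other 4, a value that rests on 2 counts, too few to set that library apart. The share of cells with ARG2 was 14% in replicate 2 of 3 dpi, against 6.77% in the next.

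The difference between mmp13a-positive and mmp13a-negative cells changed from 1 to 3 dpi, by an edgeR interaction test with 2 residual degrees of freedom, for 20 of 1673 genes (178 at an unadjusted p under 0.05), 3 of them among the genes named for that split. It moved by -0.98 for apoc1 (edgeR adjusted p = 0.00308), by 1.71 for GPI (0.0164) and by -1.88 for EPX (0.0287). Neutrophil-like cells were 24.8% and 38.2% of the mmp13a-positive cells at 1 dpi and 49.1% and 49.7% at 3 dpi.

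Transcripts of skeletal muscle and other tissues were far more abundant in the uninjured library. The 18 wells over 50000 transcripts held 94.3% of its muscle transcripts, at a median per well 167-fold that of the other wells, which argues against RNA shared by all wells as the source of that part. Without them the skeletal muscle median was still -7.10 and that of the neuron, gut, fibroblast, liver, pigment and keratinocyte genes -3.99 (quartiles -5.62 and -1.78). This argues against transcripts counted in those wells as the whole source. Leaving wells out does not remove RNA that they may have shared with other wells, so their part in the remainder is not excluded. The wells up to 50000 transcripts held 5.7%. Between medians of their clusters of at least 10 wells, muscle transcripts per well differed 1.26-fold while total transcripts differed 7.44-fold. RNA shared by all wells would give such a pattern in those clusters. Smaller classes lay further apart, with medians of 27 in 8 macrophage-like and 203 in 4 keratinocyte-like wells, so the source of that part stays open. Whole larvae against dissected tissue cannot be told apart from injury, since 0 injured libraries are of the same age as the uninjured one or come from whole larvae, and what injury changed in macrophages stays open.

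The 271 genes that differed with mmp13a followed a split of cells. Of 32 splits within libraries only the real one called as many genes, and the highest of the others gave 64. That share, 1 of 32, is the smallest this design can give, so chance is unlikely but not excluded. Without the neutrophil-like cluster 235 of these genes could be tested, 10 were still called and 204 kept their direction. The median size of the difference was then 0.24 (quartiles 0.12 and 0.49) against 0.74 with the cluster. That decides nothing about the source, since 11 of 20 leading genes of the cluster are mmp13a or genes of the split, so that a smaller difference was built in. How much of the split comes from neutrophil-like cells stays open, as does whether macrophages with mmp13a differ from those without and whether neutrophil-like cells carry the reporter or its protein taken up.

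Of genes of oxidative phosphorylation, the cell cycle and the lysosome, 32 of 70, 16 of 38 and 11 of 40 were called lower at 3 dpi, and the list calls were lost with an estimated correlation (adjusted p = 0.898, 0.852 and 0.898). A difference in transcripts per cell is argued against, since the median of the 3 lists was -1.18 in thinned cells (quartiles -1.68 and -0.67) against -1.54 before. Clusters named as other cell types are argued against too, with a median of -1.33 without them (quartiles -1.71 and -0.80). Unnamed clusters stayed in that fit. Without cluster 13 alone the median was -1.36 (quartiles -1.69 and -0.86). Leaving out cluster 13 and the named clusters together was not tried, so a part of unnamed cells in the change stays open. The age of the larvae cannot be told apart from time after injury, since 0 libraries of 3 dpi are of the same age as those of 1 dpi. The preparation of each plate stays open too, and uninjured dissected tissue of both ages, which the series lacks, would separate age from injury.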

How the results depend on the processing

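Alternatives that left out wells over 50000 transcripts, the neutrophil-like cluster or cluster 13, or that joined 2 choices, were chosen after seeing the data, as were those of the list counts other than the estimated correlation, the block and the left-out libraries. The cause was not tested except where fewer libraries, cells or genes entered by construction. Depth limits the share of cells with a gene and thinned tests: thinning left 5595 of 13901 genes. A library left alone in its group was assumed to vary like the others. Of 1334 alternative values of 60 named genes between 1 and 3 dpi, 1109 kept direction and call, 203 lost the call, 11 gained it and 11 changed sign. Of 2242 values of 112 genes in injured against uninjured, 1883 kept both, 268 lost and 55 gained the call and 36 changed sign. Of 561 values of 42 genes in the mmp13a split, 450 kept both, 98 lost and 7 gained the call and 6 changed sign. List medians lost the call in 43 of 133, 96 of 318 and 11 of 77 values, and 6 changed sign. Of 150 alternative share values of single libraries, 56 lay outside the 95% counting interval of the main value. Some of these alternatives, such as no thinning, change the measure itself.

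Counts between 1 and 3 dpi (1254) were 615 with DESeq2, 664 with RLE, 70 with library size, 643 thinned, 787 without the neutrophil-like cluster, 528 without cluster 13 and 524 thinned without other cell types. With only the 4 libraries of these times edgeR called 0, with 2555 at an unadjusted p under 0.05. Leaving out single libraries gave 14 (without replicate 2 of 1 dpi) to 3852 (without replicate 1 of 3 dpi), with 108 without replicate 1 of 1 dpi, 793 without 2 dpi, 735 without replicate 2 of 3 dpi and 559 without uninjured. Counts for injured against uninjured (2317) were 1142 with DESeq2, 348 without other cell types, 197 thinned, 484 without wells over 50000, 304 without both and 89 thinned without other cell types. Leaving out single libraries gave 1392 (replicate 2 of 1 dpi) to 4061 (replicate 1 of 3 dpi), with 1532 without replicate 1 of 1 dpi and 3922 without replicate 2 of 3 dpi. Counts for the mmp13a split (271) were 155 with DESeq2, 83 without thinning, 11 without other cell types, 12 without the neutrophil-like cluster, 41 without the library block and 178 to 320 without single libraries (180 and 178 without replicate 1 or 2 of 3 dpi).

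The labels do not say what libraries of the same number share. Spike-in transcripts made up 13.6% and 16.1% of the injured libraries numbered 2 and 4.59%, 4.19% and 5.70% of those numbered 1, but 1.19% of the uninjured library, also numbered 2, so a shared preparation is neither shown nor ruled out. With that number as a block 1966 genes were called between 1 and 3 dpi and 1702 for injured against uninjured, where 2 of the 12 lower genes named by size were still called. The deviations of same-numbered libraries correlated at 0.24 over 13901 genes, from 2 pairs.

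Lists called with an estimated correlation were 0 of 36, 0 of 36 and 1 of 21. Between 1 and 3 dpi 5 were called without other cell types and 5 when also thinned. For injured against uninjured 11 were called without other cell types, 10 thinned, 14 without wells over 50000, 12 without both and 8 thinned without other cell types. For the mmp13a split 12 were called without thinning. The neutrophil-like difference was 14.9 points in cells of at least 1000 transcripts. The NAMPT difference was -2.61 points without thinning and 3.68 thinned to 500, and the tnfa difference -13.3, -1.90 and, with at least 2 transcripts, -1.26.

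Between 1 and 3 dpi, signs changed for marco without other cell types (0.12), also without wells over 50000 (0.12) or thinned (0.45), and for NAMPT likewise (-0.19, -0.19 and -0.30). NAMPT was -0.32 without the neutrophil-like cluster, -0.21 without replicate 2 of 1 dpi, and ranged from -0.22 (without replicate 1 of 3 dpi) to 0.52 without single libraries. So did nampt2 from -1.04 to 0.55 (without replicate 2 of 1 dpi) and CLDN5 from 0.00 (without replicate 2 of 3 dpi) to 6.02. In the mmp13a split without other cell types marco was 0.044, NAMPT -0.019 and GPI -0.14, and without the neutrophil-like cluster 0.045, -0.13 and -0.25.

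For injured against uninjured, signs changed without other cell types for MPEG1 (ENSDARG00000055290 -0.095, ENSDARG00000043093 -0.58), marco (-0.18), NAMPT (-0.20), IRF8 (-0.39), INHBA (-0.24) and oxidative phosphorylation (0.054). Thinned, they changed for MPEG1 (-0.51 and -0.87), marco (-0.45), gbp1 (-0.65), stat2 (-0.45) and IRF8 (-1.09). Without wells over 50000 they changed for MPEG1 (-0.12 and -0.60), marco (-0.21), IRF8 (-0.39) and oxidative phosphorylation (0.010). Without both they changed for MPEG1 (-0.13 and -0.65), marco (-0.24), NAMPT (-0.16), IRF8 (-0.46), MYOD1 (0.12), INHBA (-0.29), oxidative phosphorylation (0.080) and growth factors (-0.26). Thinned without other cell types they changed for MPEG1 (-0.55 and -0.54), marco (-0.43), mmp13a (-0.0083), NAMPT (-0.40), SPI1 (-0.029), ptprc (-0.11), gbp1 (-0.81), stat2 (-0.23), IRF8 (-1.14), alas2 (0.39), the macrophage list (-0.11) and the microglia list, whose median was 0.17 while its test turned down. With the replicate block nampt2 was 0.033. Without single libraries MPEG1 (ENSDARG00000043093) ranged from -0.077 (without 2 dpi) to 0.86.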

Other observations

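The values in this part come from the planned lists and genes, of which those named were picked after their values were seen. The test of how the mmp13a difference changed with time was chosen after the data were seen.

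The 2 dpi library, which enters no comparison of its own, had the highest summed level of several immune lists. Antigen presentation genes summed to 3720 CPM at 2 dpi, against 2306 and 2180 CPM at 1 dpi, 3265 and 2439 CPM at 3 dpi and 945 CPM in the uninjured library. Chemokines and their receptors summed to 5813 CPM, against 4160 and 3986 CPM at 1 dpi and 5356 and 3608 CPM at 3 dpi. Dendritic cell genes summed to 1900 CPM, against 1314 and 1187 CPM at 1 dpi and 1555 and 1347 CPM at 3 dpi. The galectin gene lgals9l1 stood at 230 CPM at 2 dpi, between 488 and 601 CPM at 1 dpi and 90.4 and 49 CPM at 3 dpi, and cd74a at 200 CPM, above 39.9 and 20.4 CPM at 1 dpi and within the 176 to 350 CPM of 3 dpi. With 1 library at 2 dpi no error between replicates can be given for these values.

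Besides the 3 genes named for that split, the mmp13a difference changed between 1 and 3 dpi for 17 others, of which 9 are given, with no test of what they share. It moved up for tnfb (1.05, SE 0.22, edgeR adjusted p = 0.000982), the sheddase gene adam8a (4.08, SE 0.89, 0.00132), the fatty acid receptor gene GPR84 (1.03, SE 0.27, 0.0138) and ODC1, the first enzyme of polyamine synthesis (1.63, SE 0.42, 0.0122). It moved down for ACOD1, which makes itaconate (-1.15, SE 0.27, 0.0035), the ferritin gene fthl27 (-0.81, SE 0.17, 0.00082), the zinc exporter gene SLC30A1 (-1.81, SE 0.43, 0.00523), the chemokine gene ccl35.2 (-1.03, SE 0.22, 0.00132) and grna.2 (-2.54, SE 0.41, 6.84e-07). In mmp13a-negative cells grna.2 stood at 486 and 114 CPM at 1 dpi and at 1712 and 2181 CPM at 3 dpi. That gene leads the metaphocyte-like class, whose mean share was 0.84% at 1 dpi and 6.22% at 3 dpi. After thinning, mmp13a was found in 0 of 43 such cells of the injured libraries.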
